A study of Mus musculus with 24 samples.

How the data were processed

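Total RNA was sequenced from mesenteric arteries, the small resistance arteries that feed the intestine, of 24 male mice. Per the labels' protocols, the arteries were dissected away from the surrounding fat and the veins, ribosomal RNA was depleted and stranded TruSeq libraries were made from total RNA. The mice fall into 4 groups of 6 by genotype and time. The ieCre mice carry a tamoxifen-inducible Cre recombinase in endothelial cells and served as controls, and the ieET-1 mice additionally overexpress human endothelin-1 in the endothelium after induction. Both genotypes received tamoxifen for 5 days and were killed 16 days (short term) or 3 months (long term) later. Each library comes from 1 mouse, which is named here by its animal ID. No mouse appears at both times and no number pairs mice across groups.

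The deposited table holds, per the values themselves, a normalized signal per gene and library: each value is a whole number of reads divided by an effective library size of that library and multiplied to a scale close to CPM. The submitters' processing notes list bcl2fastq 1.8.4, FastQC, STAR 2.3.1, R 3.2.3 and edgeR 3.6.8, with no role for each. The genome build, the gene annotation and the read counter are not given in the sources used here. The table has 29021 rows, and the lowest total of any gene is 1 read. A single row carries the name ID and repeats the animal ID numbers as if they were reads, so it was left out of the recovered totals and the tests. It stood for at most 0.0993% of a library's reads (mouse 9955). Whether it entered the submitters' effective library sizes, which the main test kept, is not known. Of the 29020 gene identifiers, 28403 (97.9%) were given a symbol through the GENCODE mouse annotation, release 21 on GRCm38, which was also used for gene locations and may differ from the annotation the authors used. The table is per gene, so transcript isoforms were not analysed here. No separate row for the human transgene was used here, and reads of the human sequence enter mouse Edn1 only as far as they align there.

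Whole reads were recovered by dividing each value by the smallest positive value of its column. Within a tolerance of 0.001, 100% of the 482060 positive values came out whole. The recovered totals ran from 9635250 reads (mouse 8135) to 16181605 (mouse 9486), with a median of 13017255. A gene with 3 reads, the floor used here, has a value of 0.177 to 0.461 depending on the library. Floors and intervals of that kind cover counting error only. No library was a copy of another: over the 276 pairs of libraries, the lowest chi-square per degree of freedom was 13.1.

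The main test was limma 3.58.1 in R 4.3.3, with a trend in the variance, on log2(value + 1). Genes with a value of at least 1 in at least 6 libraries were kept, which left 14544 genes. One means model over the 4 groups used all 24 libraries (20 residual degrees of freedom), with no covariate. The unit was at first assumed to be CPM, and the table turned out to hold reads over effective library sizes, and the log scale test set for normalized values was used unchanged. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. The p-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. The comparisons were ieET-1 against ieCre at each time, their difference (the genotype by time interaction), and long against short term within each genotype. Edn1, Vegfa and Khdrbs3 were also compared with a two-sided exact permutation test of 6 against 6 libraries, 6 tests in all.

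Before the data were examined, 30 gene lists were fixed, covering vascular functions, pathways and the cell types that arteries or neighbouring tissue could bring. Lists with at least 5 tested genes were used, which left 28. The skeletal muscle and intestinal epithelium lists had 4 tested genes each and were not tested. Lists were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation. The test fry, which asks whether the genes of a list move one way on balance, was an alternative. The genes named in the text follow a rule fixed at the same time. Edn1, Vegfa and Khdrbs3 are named throughout. For a genotype comparison, up to 10 symbols in each direction are named by largest fold change among the genes that passed, and for the other comparisons up to 5 in each direction; with under 5 passing, the 10 with the smallest p are named as not passing. For each list described, 2 to 4 of the members with the smallest p are named. Predicted genes and pseudogenes are counted only, except where the text says otherwise.

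The same code was tested on simulated counts drawn from the real means and library sizes for the 14544 genes, with 100 genes changed at each of the fold sizes. For the short-term genotype comparison limma recovered 48% of genes changed 1.5-fold and 72% of those changed 2-fold, with 6 false calls among 126. For the long-term genotype comparison it recovered 40% and 80% of them, with 3 false calls among 123. A list of 11 genes raised 1.3-fold ranked 1st by camera in both, there run without the variance trend of the main test. The simulated genes varied independently around 1 mean per gene, with no correlation between genes and no differences by ID range or tissue. The rates therefore do not cover such structure in the real libraries.

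Alternatives fixed beforehand were a pseudocount of 0.25, no filter, a filter on a mean of at least 5, median-of-ratios scaling, quantile normalization, library weights, a fit of the compared groups alone, the animal ID range as an added term, and leaving out each mouse in turn. The animal IDs fall into 2 ranges within each time, and whether these mark a batch is not given in the labels. At the short term the ranges are 1 to 3 digits (2 ieCre and 3 ieET-1 mice) and 4 digits (4 and 3). At the long term the ranges are 80xx to 81xx (2 ieCre and 4 ieET-1) and 94xx (4 and 2). Within every range but 94xx the IDs of the genotypes form separate runs. At the short term these are 8 and 10 (ieCre) against 256 to 258 (ieET-1), and 8754 and 9955 to 9958 against 8987 to 8992. Means within a range, or a fit with the range as a term, may thus not hold a cohort constant. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, leaving out 4 libraries with over 10% of reads on Gm42418 or mouse 9489, and added terms for adrenal, pancreatic and adipocyte scores, each the mean log2 value of marker genes. On the recovered reads edgeR called 7, 1, 0, 434 and 1319 genes, and DESeq2 called 41, 1, 6, 794 and 1898, in the order of the comparisons above. Tables were made with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.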

Results

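Gene expression was measured by total RNA sequencing in mesenteric arteries of 24 male mice, in 4 groups of 6: ieCre controls and ieET-1 mice, which overexpress human endothelin-1 in the endothelium after tamoxifen, each killed 16 days (short term) or 3 months (long term) after 5 days of tamoxifen. Endothelin-1 is a strong vasoconstrictor peptide, and the series title asks about Vegfa isoforms and the RNA-binding splicing regulator Khdrbs3. Recovered totals per library were 13099188 ± 2032803 reads (SD, n = 6) in ieCre short term, 12808103 ± 499279 in ieET-1 short term, 13268133 ± 2442163 in ieCre long term and 12946040 ± 2043860 in ieET-1 long term. Values are reads per effective library size on a scale close to CPM. In 4 of the 24 libraries, over 10% of reads lay on Gm42418, a gene that overlaps ribosomal RNA sequence: mouse 9955 (ieCre short term, 26.6%), mouse 9491 (ieCre long term, 11.5%) and mice 8135 and 8136 (ieET-1 long term, 21.3% and 11.9%). The ieET-1 long-term group also held mouse 9489, with reads on 24399 genes against a median of 19992.5 over the libraries.

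Khdrbs3 was higher in ieET-1 than in ieCre arteries at both times. At the short term its value was 47.6 ± 5.73 in ieCre and 81.9 ± 7.83 in ieET-1 (SD, n = 6 each), a log2 fold change of 0.77 (limma, SE 0.08, adjusted p = 3.82e-05). Its long-term values were 54.2 ± 5.46 and 87.2 ± 4.18 (SD, n = 6 each), a log2 fold change of 0.68 (limma, SE 0.08, adjusted p = 0.000413). The lowest ieET-1 library lay above the highest ieCre library at each time (71.2 against 54.7, and 79.9 against 62.5), and the exact permutation p was 0.00216 both times, the smallest that 6 against 6 can give. Within the animal ID ranges the means were 50.1 in ieCre and 83.7 in ieET-1 (1 to 3 digits), 46.3 and 80.1 (4 digits), 57.5 and 85.4 (80xx to 81xx), and 52.6 and 90.9 (94xx). The IDs of the genotypes form separate runs in every range but 94xx, so these means may not hold a cohort constant. Khdrbs3 (ENSMUSG00000022332) lies on chromosome 15 from 68928420 to 69101211 in GRCm38. The change in effect between the times was -0.09 (limma, adjusted p = 0.809).

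Vegfa, which encodes the main growth factor of blood vessel formation, did not pass in either genotype comparison at the gene level. Its value was 74.2 ± 15.1 in ieCre and 67.4 ± 7.33 in ieET-1 at the short term (SD, n = 6 each), a log2 difference of -0.12 (95% interval -0.38 to 0.14; limma, adjusted p = 0.712). Long-term values were 62.2 ± 8.71 and 63.8 ± 8.72 (SD, n = 6 each), a difference of 0.04 (interval -0.22 to 0.29; limma, adjusted p = 0.999). Within ID ranges the short-term difference went both ways, with means of 58.4 and 65.3 in mice of 1 to 3 digits and 82.0 and 69.5 in mice of 4 digits, ieCre first. The long-term means within ranges were 68.6 and 67.7 (80xx to 81xx) and 59.0 and 55.9 (94xx). Vegfa (ENSMUSG00000023951) lies on chromosome 17 from 46016993 to 46032369.

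Mouse Edn1, the counterpart of the human transgene, was 35.9 ± 6.41 in ieCre and 43.9 ± 5.16 in ieET-1 at the short term (SD, n = 6 each). Its log2 difference of 0.29 (95% interval 0.04 to 0.55) did not pass across all genes (limma, adjusted p = 0.486), and the exact permutation p was 0.0519. Means within the ID ranges were 34.4 in ieCre and 44.4 in ieET-1 (1 to 3 digits), and 36.6 and 43.4 (4 digits). At the long term the values were 32.0 ± 4.73 and 31.6 ± 4.48 (SD, n = 6 each), a difference of -0.01 (interval -0.27 to 0.24; limma, adjusted p = 0.999), with 33.8 and 30.4 in 80xx to 81xx and 31.1 and 33.9 in 94xx. The difference between the times did not pass (interaction -0.31, limma, adjusted p = 0.752). Because the transgene is human, mouse Edn1 checks the genotype labels only in part. Edn1 (ENSMUSG00000021367) lies on chromosome 13 from 42301476 to 42307990.

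**Figure D1:**
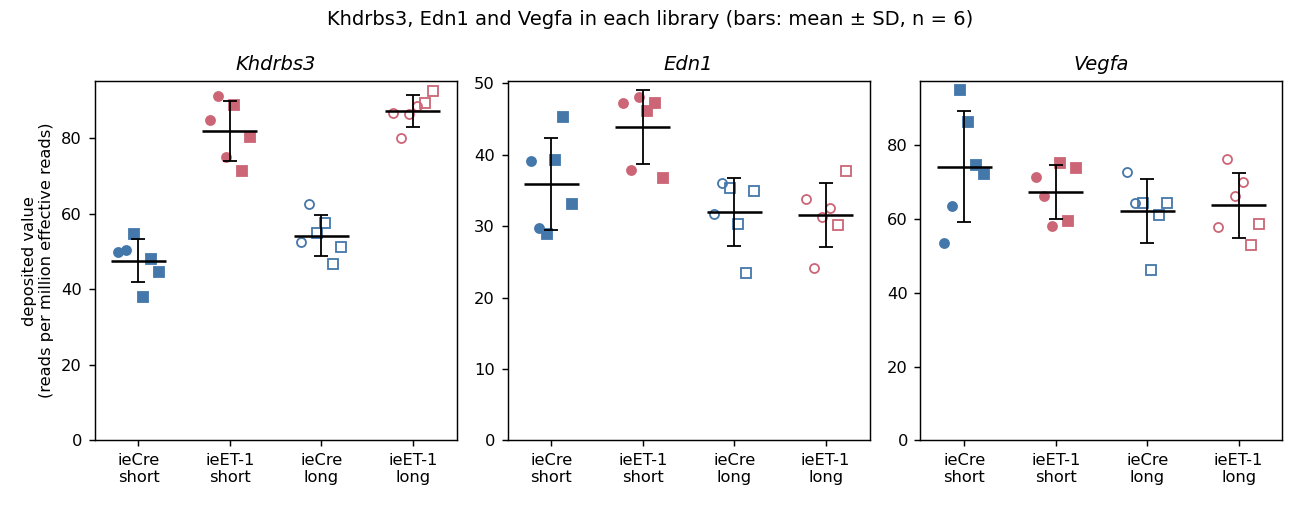
Values of Khdrbs3, Edn1 and Vegfa (vertical axes, normalized signal, a scale close to CPM) in each library of the 4 groups (horizontal axis), with circles for the first and squares for the second animal ID range of each time, and bars for the mean ± SD (n = 6). Khdrbs3 runs from 38 to 62.5 in the ieCre libraries and from 71.2 to 92.4 in the ieET-1 libraries.

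The short-term comparison asks what endothelial endothelin-1 changed soon after induction. Of the 12 calls, 6 were genes of steroid hormone synthesis, a grouping made after the calls were seen and not tested as a list, and all 6 were lower in ieET-1. Star, which carries cholesterol into mitochondria, was 88.0 ± 63.0 in ieCre and 7.66 ± 8.83 in ieET-1 (SD, n = 6 each), a log2 fold change of -3.54 (limma, SE 0.62, adjusted p = 0.0164). Hsd3b1, a steroid dehydrogenase, had the largest change of the calls on the log2(value + 1) scale, though not by the ratio of group means. It went from 118 ± 67.0 to 9.40 ± 13.7 (SD, n = 6 each, log2 -4.49, SE 0.86, limma adjusted p = 0.0333). The steroid hydroxylases Cyp11b1 (log2 -3.79, adjusted p = 0.0195), Cyp21a1 (-3.62, 0.0164) and Cyp11a1 (-3.6, 0.0329) were lower as well, and so was Cyp11b2, the aldosterone synthase (-1.38, 0.0214), which had reads in 1 of the 6 ieET-1 libraries. Cyp11b1 and Cyp11b2 are close relatives whose reads the counting could split. These enzymes are abundant in the adrenal cortex, and an adrenal score (mean log2 value of Star, Cyp11a1, Cyp11b1, Cyp21a1 and Hsd3b1) was 5.48 ± 1.41 in ieCre and 1.68 ± 1.65 in ieET-1 (SD, n = 6 each). The ieCre library of mouse 9955 had a score of 2.85, below the 3.80 of ieET-1 mice 8987 and 8992. Within ID ranges, Star was 56.6 in ieCre and 2.02 in ieET-1 (1 to 3 digits), and 104 and 13.3 (4 digits).

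In all, 12 of 14544 genes passed at the short term, 2 higher and 10 lower in ieET-1 (limma, Benjamini-Hochberg adjusted), and 1441 had an unadjusted p under 0.05 against 727 by chance. Besides the steroidogenic genes, Klhdc8a, a kelch domain protein, was 4.62 ± 2.11 in ieCre and 1.20 ± 0.554 in ieET-1 (log2 -1.30, limma adjusted p = 0.0164, n = 6 each), and Trank1 was 4.64 ± 3.49 and 0.476 ± 0.470 (log2 -1.78, limma adjusted p = 0.0164, n = 6 each). Ssbp4, a single-stranded DNA binding protein, was 25 ± 2.87 and 16.7 ± 1.90 (log2 -0.55, limma adjusted p = 0.0164, n = 6 each). The other higher gene beside Khdrbs3 was Rpl3-ps1, a processed pseudogene of the ribosomal protein gene Rpl3, at 1.27 ± 0.431 and 11 ± 3.79 (log2 2.36, limma adjusted p = 0.0164, n = 6 each). Its reads can be shared with Rpl3. Within ID ranges, Rpl3-ps1 was 1.45 and 13.7 (1 to 3 digits) and 1.18 and 8.24 (4 digits), ieCre first. The last lower call was the unnamed ENSMUSG00000095742, at 26.8 ± 4.84 and 13 ± 3.45 (log2 -1.02, limma adjusted p = 0.0432, n = 6 each). It and Rpl3-ps1 were named after their values were seen. With the compared groups alone 4 genes passed, 3 higher and 1 lower, and 2 of the 4 were among the 12. The count was 1, Khdrbs3, with the adrenal score as a term, 19 with the ID range as a term, and 1 without mouse 9957, 256, 257 or 258. It was 55 with library weights, 41 by DESeq2, 24 without the 4 libraries high in Gm42418 and 21 without mouse 9955. With each of the 12 mice left out in turn, Khdrbs3 kept its call in every fit, while each of the other 11 calls was lost in some, from 4 (Klhdc8a) to 11 (ENSMUSG00000095742) of the fits, Star in 7 and Hsd3b1 in 9.

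**Figure D2:**
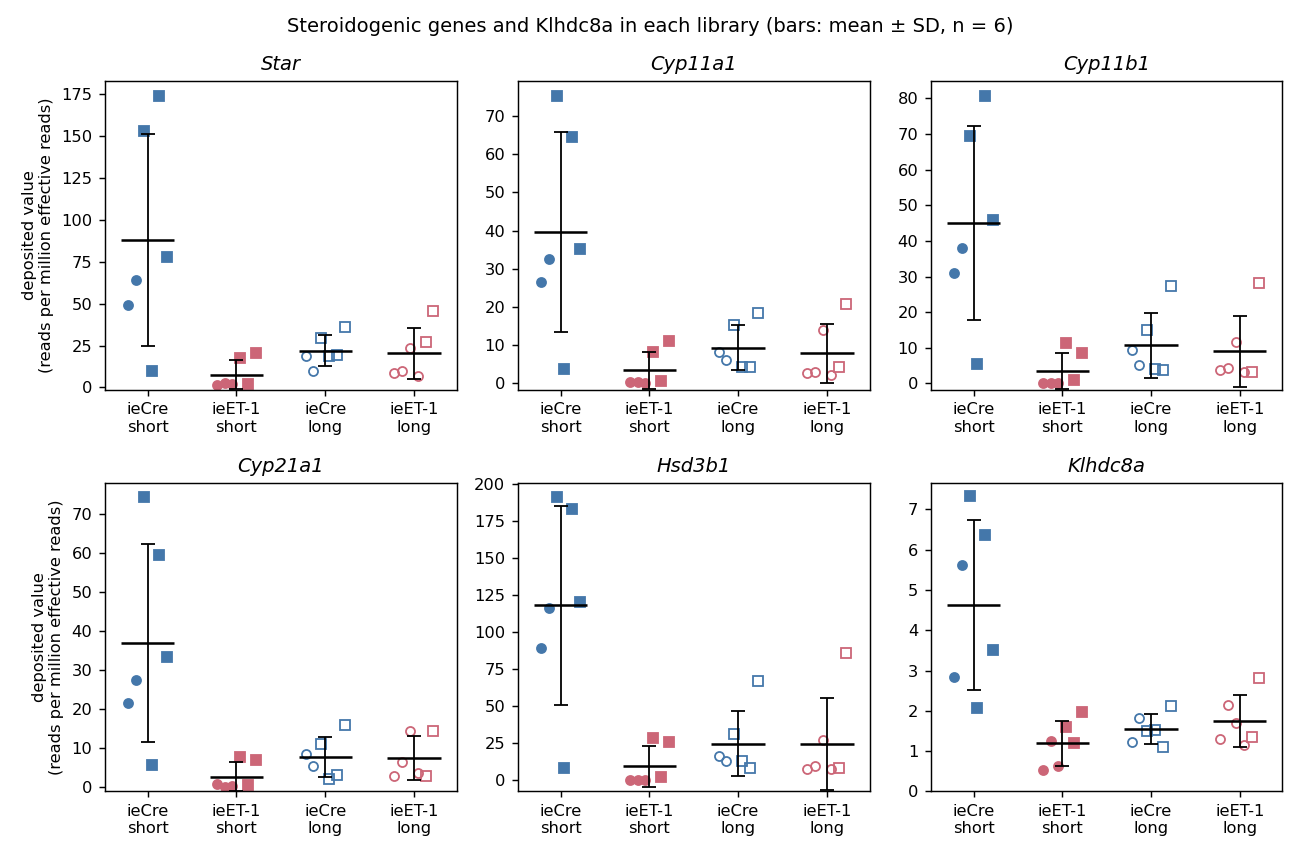
Values of 5 steroidogenic genes and Klhdc8a (vertical axes, normalized signal, a scale close to CPM) in each library of the 4 groups (horizontal axis), with circles for the first and squares for the second animal ID range of each time, and bars for the mean ± SD (n = 6). Star averages 88.0 in ieCre and 7.66 in ieET-1 at the short term, and 21.9 and 20.3 at the long term.

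Among the gene lists, matrix and contractile genes lay lower in ieET-1 at the short term, each by a small amount over many members. Of the 22 genes of extracellular matrix remodelling, 20 had lower values in ieET-1, with a median log2 difference of -0.38 (camera, adjusted p = 1.05e-05; adjusted p = 0.844 with an estimated correlation). Examples are elastin (Eln, -0.76), the collagen gene Col5a1 (-0.54) and the elastin crosslinker Loxl1 (-0.51). All 16 genes of contractile smooth muscle had lower values, with a median of -0.24 (camera, adjusted p = 0.000636; adjusted p = 0.844 with an estimated correlation), among them Tagln (-0.42) and Lmod1 (-0.52), both actin-binding proteins of smooth muscle. Splicing regulators had a median of 0.11 (camera, adjusted p = 0.0342; adjusted p = 0.844 with an estimated correlation), with Srsf1 at 0.17 and Srsf3 at 0.27. This list did not pass without mouse 8, 10, 9957, 256, 8987 or 8992 (highest adjusted p = 0.155). No matrix or contractile gene passed over all genes or adjusted over the list alone (0 of 22 and 0 of 16), and 1 of 19 splicing regulators passed both ways, Khdrbs3. The splicing list was not tested without Khdrbs3, so its call may in part repeat the result for that gene. With the adrenal score given above as a term the camera adjusted p was 5.19e-08 for matrix, 0.0622 for contractile and 0.0279 for splicing genes. With all 3 tissue scores contractile genes were at 0.274. None of the 8 endothelin system genes and none of the 10 VEGF genes passed over all genes or adjusted over the list alone (0 and 0), with Ednrb, an endothelin receptor, at 0.19 and Pgf, a VEGF family ligand, at -0.25.

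At the long term Khdrbs3 was the single gene that passed (1 of 14544, limma, Benjamini-Hochberg adjusted), and 435 genes had an unadjusted p under 0.05 against 727 by chance. The next smallest p-values did not pass (limma, adjusted p = 0.999 for each). They belonged to Gimap5, a GTPase of lymphocytes (9.13 in ieCre and 6.67 in ieET-1), Lrrc10b (24.5 and 18.3), the receptor tyrosine kinase Erbb4 (2.69 and 5.41), the RNA-binding Stau2 (12.2 and 15.3), Ssbp4 (32.6 and 25.2), the histone deacetylase Hdac9 (9.81 and 13.1), Zfand4 (1.67 and 2.61), the immunoglobulin segment Igkv6-23 (1.94 and 0.645) and the synaptic adhesion gene Nlgn3 (1.73 and 2.98). The steroidogenic genes did not pass, with Star at 21.9 ± 9.27 and 20.3 ± 15 (SD, n = 6 each) and adrenal scores of 3.6 ± 0.84 and 3.30 ± 1.07.

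At the long term 5 lists passed, none of them among those of the short term, and no member of the 5 passed over all genes. Mitochondrially encoded transcripts had a median log2 difference of -0.35, with all 6 tested genes lower (camera, adjusted p = 0.000911; adjusted p = 0.786 with an estimated correlation), among them the respiratory chain genes mt-Nd2 (-0.57) and mt-Nd1 (-0.40). Cholesterol synthesis genes had a median of 0.12 over 13 genes (camera, adjusted p = 0.0172; adjusted p = 0.786 with an estimated correlation), with the rate-controlling Sqle at 0.34, and cell cycle genes a median of -0.30 over 12 genes (camera, adjusted p = 0.0422; adjusted p = 0.817 with an estimated correlation), with Birc5, a mitotic protein, at -0.50. Lymphatic markers had a median of -0.27 over 5 genes (camera, adjusted p = 0.0192; adjusted p = 0.786 with an estimated correlation), and Pdpn (-0.49) was the 1 gene that was lower adjusted over the list alone. Markers of pancreatic acinar cells, a tissue outside the artery, had a median of 1.16 over 9 genes (camera, adjusted p = 0.0172; adjusted p = 0.817 with an estimated correlation), with Pnlip, the pancreatic lipase, at 2604 in ieCre and 6486 in ieET-1. The Pnlip log2 difference ran from 0.417 to 2.027 over mice left out and was -0.28 without the 4 libraries high in Gm42418. The ID range moved with the groups, since 4 of the 6 ieET-1 and 2 of the 6 ieCre mice came from 80xx to 81xx. With it as a term the adjusted p was 0.0954 for mitochondrial, 0.984 for cell cycle and 0.224 for pancreatic genes, and 0.00101 and 0.0119 for cholesterol synthesis and lymphatic genes. Without mouse 9489 these last lists did not pass (0.2 and 0.0626), nor did cholesterol synthesis without 8088 or 8152, or lymphatic genes without 8088, 8089 or 8135. Cell cycle genes did not pass without 9486, 9487, 8134, 8135, 8136, 8152 or 9490 (highest 0.923), and pancreatic genes without 9491, 8134, 8135, 8136 or 9490 (highest 0.502). Without the 4 libraries high in Gm42418, cell cycle, lymphatic and pancreatic genes did not pass (0.418, 0.141 and 0.769).

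Whether the effect of genotype changed with time was tested by the interaction. No gene passed (0 of 14544, limma, smallest adjusted p = 0.752), 731 genes had an unadjusted p under 0.05 against 727 by chance, edgeR called 0 and DESeq2 called 6. The 10 smallest p-values belonged, in order, to Klhdc8a (1.39), Trank1 (1.84), Cyp21a1 (3.54), Galnt16 (0.50), Prss35 (1.91), Zfp605 (-0.75), Star (3.24), the steroid reductase Srd5a2 (2.34), Cyp11b1 (3.44) and the collagen gene Col6a5 (1.48), given as the change in log2 effect. All but Zfp605 had a lower mean in ieET-1 than in ieCre at the short term. Of the 28 lists, 2 passed. Matrix genes had a median change of 0.44 (camera, adjusted p = 0.00388), with Fbn1, a microfibril protein, at 0.53 and the protease Mmp2 at 0.48, and contractile genes a median of 0.39 (camera, adjusted p = 0.00865), with Itga8, an integrin, at 0.68 and the smooth muscle actin Acta2 at 0.48, which was -0.19 after quantile normalization. Both had adjusted p = 0.817 with an estimated correlation, and without mouse 9489 they were at 0.0755 and 0.0517 (camera, adjusted p). Contractile genes did not pass without 8987 or 9487 either (0.0984 and 0.109), nor with the adrenal score or all 3 scores as terms (0.102 and 0.295). No member of either list passed over all genes or adjusted over the list alone (0 of 22 and 0 of 16). With the ID range as a term matrix and contractile genes kept their calls (camera, adjusted p = 9.07e-05 and 0.0152). Macrophage and cholesterol synthesis lists then also passed as higher, and splicing, adipocyte, lymphatic and immediate early lists as lower. With that term and an estimated correlation no list passed the interaction (camera, lowest adjusted p = 0.748). Across genes the log2 fold changes of the genotype comparisons had a Pearson r of -0.07 (Spearman -0.09; Pearson r 0.19 with the ID range as a term, 0.09 with library weights, 0.28 without the 4 libraries high in Gm42418 and -0.16 without mouse 9489), where genes are not independent replicates. Khdrbs3 was the 1 gene called at both times.

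Between the short and the long term, collagen and matrix genes were lower in ieCre arteries and several adipocyte genes were higher. Col1a1 was 918 ± 328 at the short and 313 ± 208 at the long term (SD, n = 6 each; log2 -1.66; limma, adjusted p = 0.0027), Col1a2 was 2493 ± 516 and 827 ± 243 (-1.61; limma, adjusted p = 0.000171, n = 6 each) and Col3a1 was 4504 ± 756 and 1555 ± 690 (-1.61; limma, adjusted p = 0.000493, n = 6 each). The progesterone receptor Pgr (-1.91) and Vwf, the von Willebrand factor of endothelium (-1.51), were also lower. Leptin (Lep), a hormone of fat cells, was 14.5 ± 8.65 and 112 ± 48.7 (log2 2.90; limma, adjusted p = 6.1e-05, n = 6 each), and Npr3, the clearance receptor of natriuretic peptides, was 20.5 ± 10.5 and 90.2 ± 26.0 (2.16; limma, adjusted p = 3.14e-05, n = 6 each). Nnat (1.73), the transcription factor Dmrt2 (1.49) and Prr32 (1.42) completed the largest rises, and Prr32 averaged 0.0360 at the short term, below the floor. In all 480 genes passed, 281 higher and 199 lower (limma), with 2610 at an unadjusted p under 0.05.

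Of the 22 matrix genes, 8 fell over all genes and 16 fell adjusted over the list alone (median -0.69, camera adjusted p = 2.88e-15), including Fbn1 (-1.09) and Mmp2 (-1.0). This list had adjusted p = 0.0583 with an estimated correlation. Of 12 adipocyte markers, 4 rose over all genes, and 6 rose and 1 fell adjusted over the list alone (median 0.56, camera adjusted p = 0.000129; adjusted p = 0.33 with an estimated correlation), including the lipid droplet protein Cidec (1.09), the triglyceride synthesis enzyme Dgat2 (1.13) and the fatty acid binding Fabp4 (0.64). Of 9 lymphocyte markers, 1 rose over all genes and 4 adjusted over the list alone (median 0.56, camera adjusted p = 0.000849; adjusted p = 0.33 with an estimated correlation). Cd79b of B cells was 0.93 and Cd3d of T cells 0.77, the latter not passing over all genes. All 12 cell cycle genes had lower values (median -0.79, camera adjusted p = 0.000402; adjusted p = 0.563 with an estimated correlation), with none past the threshold over all genes or adjusted over the list alone (0 and 0), as for Ccna2 (-0.89) and Cdk1 (-0.95). Circadian clock genes had a median of -0.34 (camera adjusted p = 0.00777; adjusted p = 0.303 with an estimated correlation), again with 0 members passing either way, Npas2 at -0.53 and Per2 at -0.55. Adventitial fibroblast markers had a median of -0.30 (camera adjusted p = 0.00777; adjusted p = 0.371 with an estimated correlation), with 1 of 11 lower over all genes, Serpinf1 (-0.41), and 4 lower adjusted over the list alone, Col14a1 (-0.39) among them.

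Redox, cholesterol, lymphatic and hypoxia lists also passed in ieCre with the preset correlation and not with an estimated one, with at most 1 member of each called over all genes. NADPH oxidases and antioxidant enzymes had a median of 0.24 (camera adjusted p = 0.0125), with 1 of 16 higher over all genes, the mitochondrial superoxide dismutase Sod2 (0.31), and 2 adjusted over the list alone. Cholesterol synthesis genes had a median of 0.23 (camera adjusted p = 0.0132), with 1 of 13 higher over all genes, Insig1 (0.55), a sterol sensor, and 4 adjusted over the list alone. Both had adjusted p = 0.371 with an estimated correlation. Lymphatic markers had a median of 0.27 (camera adjusted p = 0.0212; adjusted p = 0.33 with an estimated correlation), with 0 of 5 higher over all genes and 2 adjusted over the list alone, where Mmrn1 was at 0.53. Hypoxia response genes had a median of 0.21 (camera adjusted p = 0.0312; adjusted p = 0.223 with an estimated correlation), with 0 of 11 higher over all genes and 3 adjusted over the list alone, where the hexokinase Hk2 was at 0.55. Hypoxia genes did not pass without mouse 8, 9958, 8088 or 9487, lymphatic genes without 10 or 8088, and cholesterol synthesis without 8 (0.0541) or without the 4 libraries high in Gm42418 (0.0811). With each of the 12 mice left out in turn, Sod2 and Cd79b lost their calls in 9 fits, Fabp4 and Serpinf1 in 8 and Insig1 in 6 (highest adjusted p = 0.137). Single genes of lists that did not pass also changed: Mme (0.80), a protease that degrades endothelin, rose, and angiotensinogen (Agt, -1.22), the interferon gene Oasl2 (-0.50) and the splicing factor Srsf6 (-0.34) fell. Oasl2 lost its call in 5 and Srsf6 in 7 of the 12 fits. The adipocyte score was 6.6 ± 0.14 at the short and 7.23 ± 0.24 at the long term, and the adrenal score 5.48 ± 1.41 and 3.6 ± 0.84 (SD, n = 6 each). With adrenal, pancreatic and adipocyte scores as terms 20 genes passed in place of 480, the matrix list kept an adjusted p of 6.11e-07 (camera), and the adipocyte list, whose genes make up that score, was at 0.553. Lymphocyte (0.132), cell cycle (0.0687), lymphatic (0.393) and hypoxia genes (0.217) did not pass with the 3 scores, while redox, fibroblast, circadian and cholesterol genes did (0.0206, 0.0206, 0.00225 and 0.000919). The 20 genes were 3 higher and 17 lower. In ieCre the adipocyte score ran from 6.41 to 6.79 at the short and 6.98 to 7.63 at the long term, without overlap. That term is thus largely confounded with time, and calls lost with the 3 scores cannot tell tissue share from time. The count of 480 fell to 317 without mouse 9955, 290 without 9958, 272 without 9485, 275 without 9486 and 285 without 9491. It rose to 2220 with library weights and 794 by DESeq2.

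In ieET-1 arteries the same contrast gave more calls, 1260 genes with 767 higher and 493 lower (limma), and 3719 at an unadjusted p under 0.05. No gene passed the interaction, so a difference from ieCre was not shown for any single gene. Under quantile normalization the split was 563 higher and 600 lower. Col1a1 was 720 ± 174 and 235 ± 103 (SD, n = 6 each; log2 -1.69; limma, adjusted p = 0.00123), and Col3a1 was 3535 ± 817 and 1244 ± 520 (-1.57; limma, adjusted p = 0.000475, n = 6 each). Pgr (-2.08) and the mitotic genes Ckap2 (-1.58) and Pbk (-1.51) were lower too. Lep was 17.5 ± 8.56 and 119 ± 43.9 (log2 2.74; limma, adjusted p = 9.24e-05, n = 6 each), and Dmrt2 (2.23), the retinoic acid degrading enzyme Cyp26b1 (2.14), the pancreatic water channel Aqp12 (2.11) and Myo5c (2.0), a myosin of exocrine glands, were higher. Aqp12 lost its call in 9 and Myo5c in 2 of 12 fits with a mouse left out. Npr3 (1.94) was higher and Agt (-0.99) lower, as in ieCre. Mouse Edn1 was lower at the long term (log2 -0.47, limma adjusted p = 0.0196), where its change in ieCre was -0.16 (limma, adjusted p = 0.525). The Edn1 call in ieET-1 was lost without mouse 258 (limma, adjusted p = 0.0523) or mouse 8135 (log2 -0.39). Genes called in both genotypes numbered 178 higher in both and 111 lower in both, against 14.8 and 6.75 for independent lists, with 0 in opposite directions (Pearson r of fold changes across genes 0.54, Spearman 0.48).

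**Figure D3:**
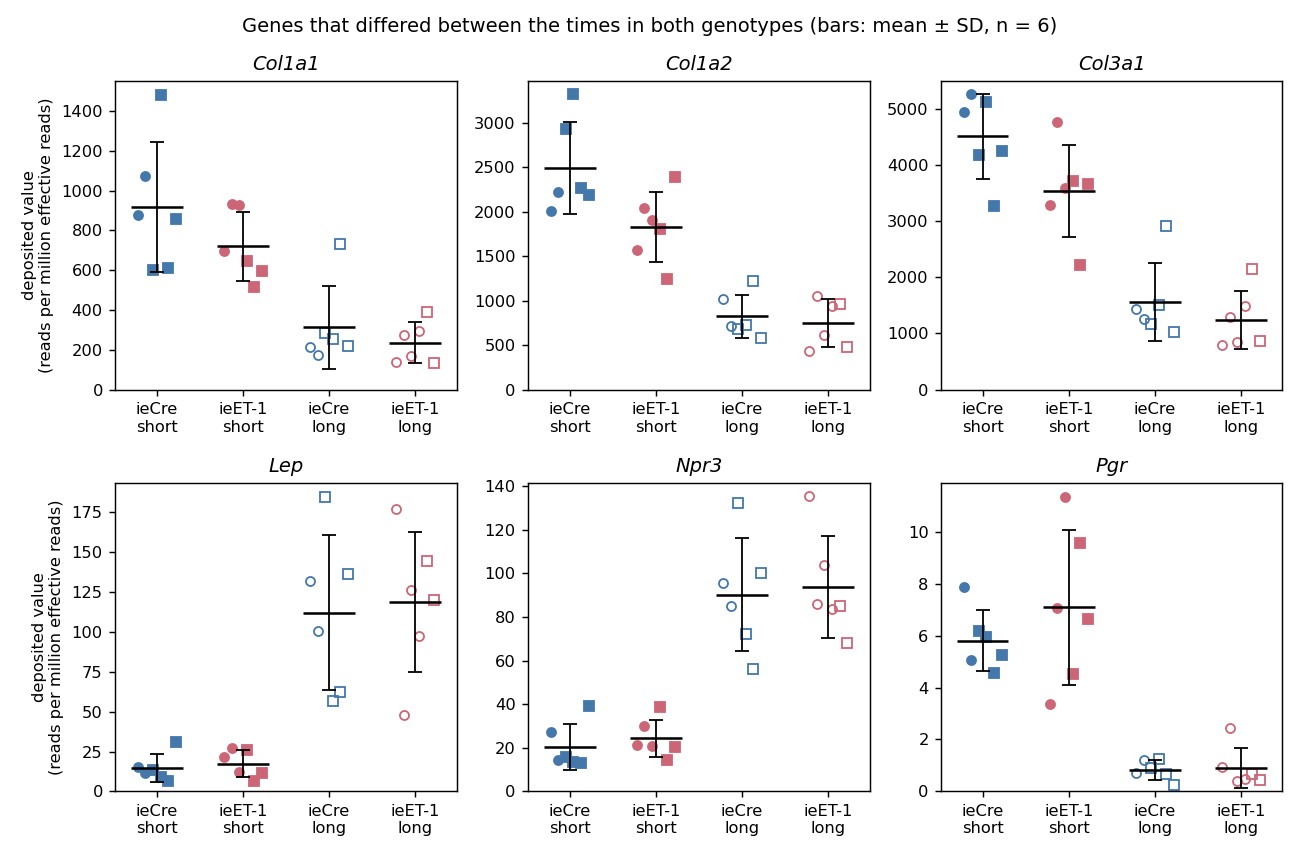
Values of 6 genes that differed between the times in both genotypes (vertical axes, normalized signal, a scale close to CPM) in each library of the 4 groups (horizontal axis), with circles for the first and squares for the second animal ID range of each time, and bars for the mean ± SD (n = 6). Col1a1 averages 918 and 720 at the short term and 313 and 235 at the long term, and Lep 14.5 and 17.5 against 112 and 119, ieCre first.

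Matrix genes fell in ieET-1 as well, with 6 of 22 lower over all genes and 8 adjusted over the list alone (median -0.42, camera adjusted p = 0.000214; adjusted p = 0.5 with an estimated correlation). Col1a2 was at -1.34 and Fbn1 at -0.56. Cholesterol synthesis rose, with 4 of 13 genes higher over all genes and 6 adjusted over the list alone (median 0.42, camera adjusted p = 0.000233; adjusted p = 0.432 with an estimated correlation). The 4 were Sqle (0.79), Fdft1 (0.57), Lss (0.64) and Insig1 (0.57), the first 3 of them enzymes that make squalene or turn it into sterol. All 12 cell cycle genes had lower values (median -0.86, camera adjusted p = 0.000272; adjusted p = 0.605 with an estimated correlation), with 0 past the threshold over all genes or adjusted over the list alone, as for Ccna2 (-1.22) and the proliferation marker Mki67 (-1.10). All 12 interferon response genes had lower values too (median -0.42, camera adjusted p = 0.00217; adjusted p = 0.605 with an estimated correlation), with Ifit1 (-0.92) lower over all genes, 1 of 12, and 4 adjusted over the list alone. Splicing regulators had a median of -0.17 (camera adjusted p = 0.00217; adjusted p = 0.432 with an estimated correlation), with 3 of 19 lower over all genes, Srsf6 (-0.30) and the kinases of splicing factors Clk1 (-0.32) and Clk4 (-0.30), and 4 adjusted over the list alone. Circadian clock genes had a median of -0.29 (camera adjusted p = 0.0108; adjusted p = 0.432 with an estimated correlation), with Per1 (-0.89) lower over all genes, 1 of 14, and 0 adjusted over the list alone. With each of the 12 mice left out in turn, Per1 lost its call in 11 fits, Ifit1 and Clk4 in 8, Clk1 in 5 and Srsf6 in 4 (highest adjusted p = 0.106).

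Of the cell type marker lists, adipocyte, fibroblast and pancreatic markers passed for time in ieET-1 with the preset correlation and not with an estimated one. Adipocyte markers had a median of 0.33 (camera adjusted p = 0.00964; adjusted p = 0.605 with an estimated correlation). Of 12 markers, 4 rose over all genes, among them Dgat2 (1.33) and Plin1 (0.80), which coats lipid droplets, and 1 fell, the fat cell protease Cfd (-1.08). Adjusted over the list alone 5 rose and 1 fell. Adventitial fibroblast markers had a median of -0.31 (camera adjusted p = 0.0108; adjusted p = 0.605 with an estimated correlation), with 1 of 11 lower over all genes, Cd34 (-0.66), and 5 adjusted over the list alone. Pancreatic acinar markers had a median of 2.52 (camera adjusted p = 0.00818; adjusted p = 0.767 with an estimated correlation), with 0 of 9 passing over all genes or adjusted over the list alone and the elastase Cela2a at 549 and 3908. Single genes that rose were the macrophage receptor Csf1r (0.51), the VEGF co-receptor Nrp2 (0.58), the tight junction protein Cldn5 (0.44), the glucose transporter Slc2a1 (0.63) and Hk2 (1.01). With a mouse left out, Nrp2 lost its call in 5, Cldn5 in 4 and Plin1 in 1 of 12 fits. The adipocyte score was 6.72 ± 0.32 at the short and 7.22 ± 0.42 at the long term, the pancreatic score 8.49 ± 1.48 and 10.9 ± 2.21 and the adrenal score 1.68 ± 1.65 and 3.30 ± 1.07 (SD, n = 6 each). With all 3 scores as terms 117 genes passed in place of 1260 and the matrix list was at 0.0239 (camera, adjusted p). Fibroblast (0.158), cell cycle (0.109), adipocyte (0.915) and pancreatic lists (0.926) did not pass then, the last 2 sharing genes with the scores, while splicing (0.00918), circadian (0.0281), interferon (0.0281) and cholesterol lists (2.36e-05) did. Adipocyte genes did not pass without mouse 8134 (0.0819), and fibroblast and adipocyte genes did not without the 4 libraries high in Gm42418 (0.0816 and 0.0549). Without the 4 libraries high in Gm42418, 603 passed, and without mouse 258 or 8136 698 and 813. DESeq2 called 1898. Each ID range belongs to 1 time, so within-range values cannot be had for a contrast of times.

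**Figure D4:**
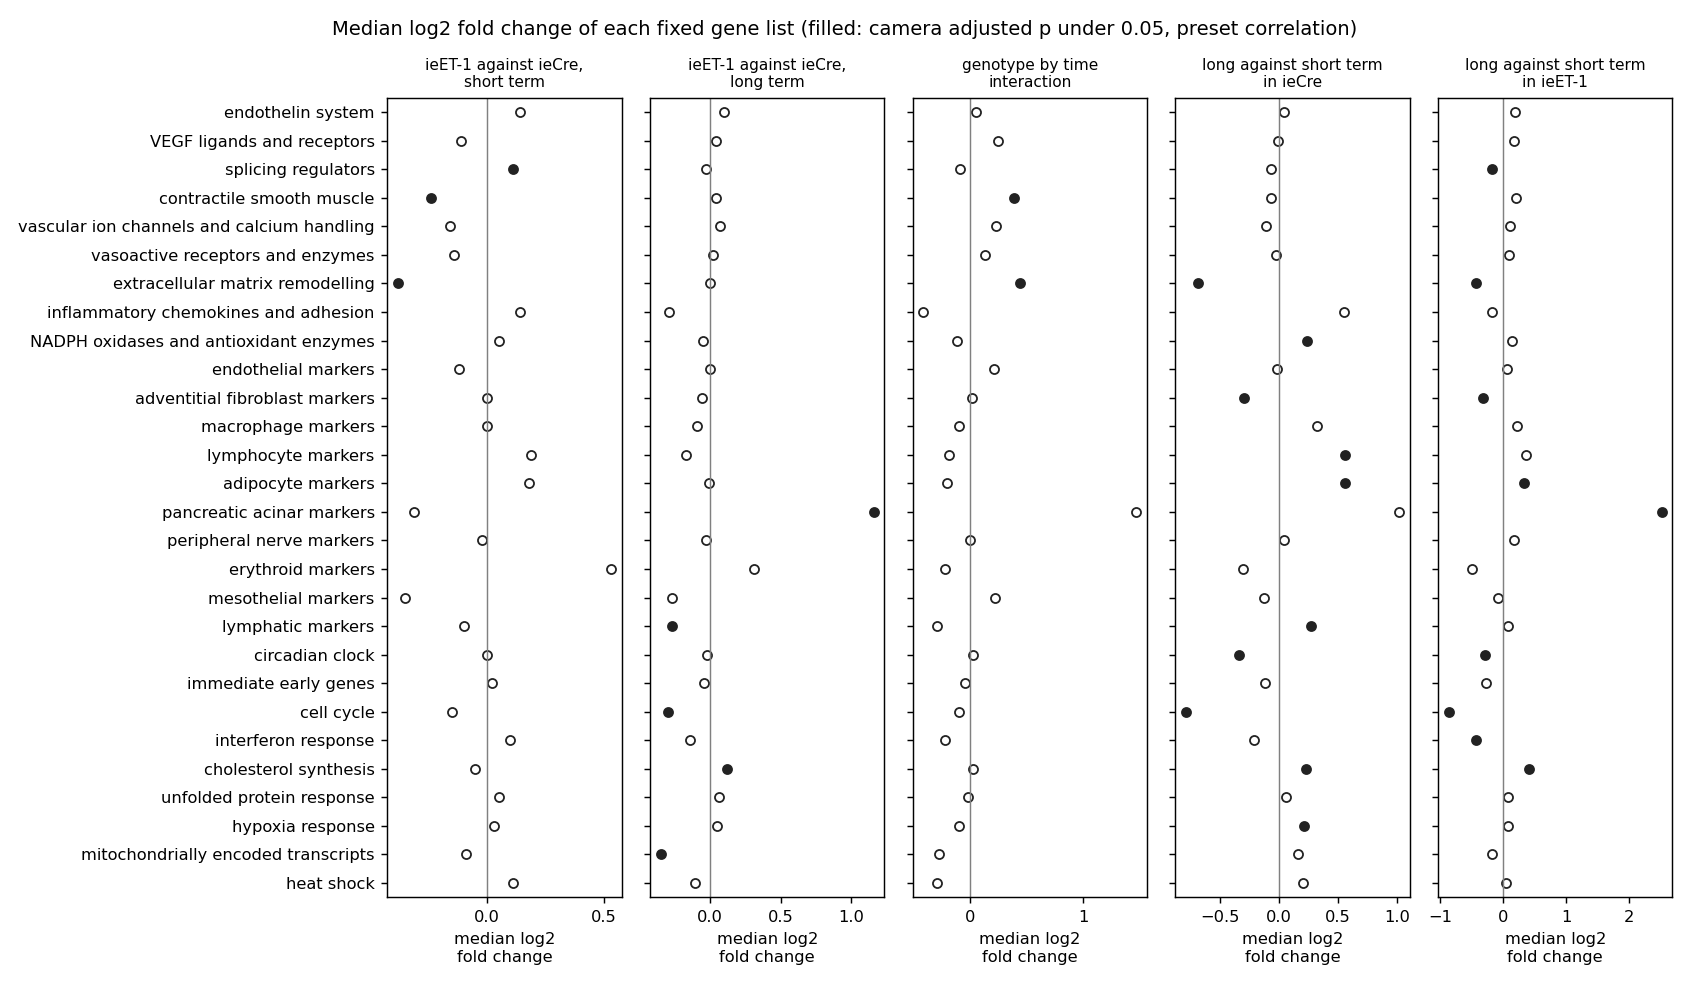
Median log2 fold change (horizontal axes) of each of the 28 tested gene lists (vertical axis) in the 5 comparisons, with filled circles where the camera adjusted p lay under 0.05 with the preset correlation and open circles elsewhere. Matrix genes lie at -0.38 for genotype at the short term, and at -0.69 and -0.42 for long against short term in ieCre and ieET-1.

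The other 13 lists passed in none of the 5 comparisons (camera, preset correlation, no added term). Their lowest adjusted p over the comparisons was 0.386 for the endothelin system, 0.131 for VEGF ligands and receptors, 0.133 for vascular ion channels, 0.194 for vasoactive receptors, 0.176 for inflammatory chemokines, 0.145 for endothelial markers and 0.0708 for macrophage markers. It was 0.843 for peripheral nerve, 0.116 for erythroid and 0.271 for mesothelial markers, 0.284 for immediate early genes, 0.143 for the unfolded protein response and 0.138 for heat shock genes. With the ID range as a term, 4 of the 13 passed in a comparison with the preset correlation and none with an estimated one. For genotype these were erythroid markers at the short term (camera adjusted p = 0.0133; 0.906 with an estimated correlation) and the long term (0.00101; 0.55), and at the long term macrophage markers (0.00798; 0.893), the unfolded protein response (0.00798; 0.55) and immediate early genes (0.00101; 0.55), with 0 members of each called. Macrophage and immediate early genes then also passed the interaction (0.0176 each; 0.764 and 0.748 with an estimated correlation), and macrophage markers passed for time in ieET-1 (0.0175; 0.774). Heat shock, mesothelial and nerve lists passed in some comparison with tissue scores as terms, and VEGF and ion channel lists when some single mice were left out. These fits used the preset correlation only, and an estimated one was not tried with them.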

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

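Chosen only after the results they bear on had been seen were the test of ribosomal RNA carry-over, the test of chromosome 15 and the fits with tissue scores as terms. Of 62 groups of 6 libraries examined for a library far from the others, 9 held one, where chance gives about 1 in 20 groups. In ieCre short term, mouse 9955 had reads on 18765 genes (others 19914 to 20218), 26.62% of reads on Gm42418 (others up to 1.42%) and the lowest adrenal score, 2.85 (others 5.28 to 6.69). In ieET-1 long term, mouse 9489 had reads on 24399 genes (others 19064 to 20414), and 2242 of these genes had reads in no other library. Gm42418 took 11.49% of reads in mouse 9491 (ieCre long term, others up to 1.403%) and 0.106% in mouse 257 (ieET-1 short term, others up to 0.048%). Trank1 stood at 11.23 in mouse 8754 (ieCre short term, others up to 4.77), Ssbp4 at 13.01 in mouse 258 (ieET-1 short term, others from 16.6), and Cyp11b2 at 0.1417 in mouse 8992 (ieET-1 short term, others at 0). For matrix and contractile genes the difference in genotype effect between the times passed as a list with the preset correlation (camera, adjusted p = 0.00388 and 0.00865). Both lists had adjusted p = 0.817 with an estimated correlation, and neither passed without mouse 9489 (camera, adjusted p = 0.0755 and 0.0517). No single gene passed that test.

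Steroidogenic genes were lower in ieET-1 than in ieCre at the short term. Dilution by ribosomal RNA carry-over is argued against, since Gm42418 took at most 0.106% of reads in the ieET-1 libraries, where the genes were lower, and the 1 short-term library high in it, mouse 9955, is an ieCre library. A candidate explanation is adrenal tissue in some libraries. Within groups, 5 adrenal cortex genes not used to find the pattern followed the called genes with a median Spearman rho of 0.36, between the bounds set beforehand. Of the 5 only Mc2r passed after adjustment (rho 0.64, Pearson r 0.75, one-sided permutation p adjusted over the 5 genes 0.0145, rho 0.66 without the 2 farthest libraries). Nr0b1, another of the 5, averaged at most 0.1 in any group, below the floor, so it could show little. Scarb1, Mrap and Fdx1 averaged 37.9, 19.4 and 16.3 in ieCre and 26.5, 17.4 and 11.3 in ieET-1 at the short term. Star went from 88.0 to 7.66 there. Much of the signal of these 3 genes thus did not move with the called genes, so the median rho cannot decide for or against adrenal tissue. The cortex genes Akr1b7 (log2 -2.88), Nr5a1 (-1.44) and Fdxr (-0.87) were also lower in ieET-1 at the short term. They did not pass (limma, adjusted p = 0.0675, 0.0675 and 0.0728). Lower values alone cannot tell adrenal tissue from an effect on steroidogenic cells, so this stays open. Adrenal tissue as the whole cause of the other short-term calls is argued against, since 1 of 5, Khdrbs3, passed with the adrenal score as a term (0.93, limma adjusted p = 0.00213), while Ssbp4 and Rpl3-ps1 went from -0.55 (SE 0.10) to -0.59 (SE 0.15) and from 2.36 (SE 0.41) to 2.35 (SE 0.64) and lost their calls through the larger error, and Klhdc8a and Trank1 shrank from -1.30 to -0.41 (SE 0.23) and from -1.78 to -0.30 (SE 0.27), so that for these 2 it stays open. An effect of the endothelin-1 genotype on steroidogenic cells was not tested apart from this and stays open.

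Khdrbs3 was higher in ieET-1 at both times, beside other genes of chromosome 15 with small genotype p-values. Tissue from adrenal gland, pancreas or fat is argued against, since with the 3 scores as terms its log2 fold change was 0.99 at the short and 0.67 at the long term (limma, adjusted p = 0.00191 and 0.00075). Reads shared with its paralogs are argued against as well, since Khdrbs1 was at -0.08 (SE 0.07, mean of both times) and Khdrbs2 averaged at most 0.0741 in any group. A segment of chromosome 15 that differs between the mouse lines is a candidate explanation that stays open: 17 of 554 other genes there (3.07%) against 1.54% elsewhere had a genotype p under 0.01 (one-sided Fisher's exact p = 0.00788), which is 0.158 after adjustment over 20 chromosomes, a requirement added after that p was seen. A response to endothelin-1 itself was not separated from the line and stays open.

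Matrix genes were lower at the long than at the short term in both genotypes. A lower share of vessel wall is argued against, since the median of the matrix list lay below those of the contractile and endothelial lists by gaps of -0.62 and -0.67 in ieCre and -0.62 and -0.49 in ieET-1. A lower share of adventitial fibroblasts cannot be told apart, since the gap to the fibroblast list was -0.39 in ieCre and -0.11 in ieET-1. Age or cohort likewise cannot be told apart from time after tamoxifen, since 0 of the long-term mice were killed as early as the short-term mice, and a change of matrix expression with age is a candidate explanation that was not tested.

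Other splits of the same libraries were drawn for each count of genes, 100 per comparison with the real one included. For genotype at the short term 2 of 100 gave as many as the real 12, under the bound of 5 set beforehand. The highest other gave 17, more than the real split. It was the real split with mice 9955 and 8987 exchanged, so 5 of 6 ieET-1 libraries stayed on 1 side. It thus kept most of the genotype contrast and says little about chance. Chance is made less likely by the count of splits and is not excluded. The split with 17 genes put the libraries with low adrenal scores together (mean score 1.52 against 5.64). For genotype at the long term 5 of 100 gave as many as the real 1, so chance cannot be excluded for the count. The highest other gave 1852 genes, which points to a structure of the samples: each side of it held 5 of 6 libraries of 1 ID range, and with the ID range as a term the long-term count was 1. For the interaction the real count was 0, which all 100 reach whatever the data, so the splits say nothing about chance there (highest other 3). For long against short term in ieCre 2 of 100 gave as many as the real 480. In ieET-1 1 of 100, the real one, gave as many as 1260. Both lie under the bound set beforehand, but 100 splits do not exclude chance. The highest others were 729 in ieCre, above the real count, and 119 in ieET-1, far below it. The split with 729 genes had 3 long-term libraries on each side and mean pancreatic scores of 10.46 and 8.11. It also followed the ID ranges in part, with mice 8088 and 8089 on 1 side and mice 8 and 10 on the other. Each of these pairs is all the ieCre mice of its range. As many calls as in ieCre can thus arise without a difference in time. Whether ID range or tissue gave them was not tested. The split with 119 genes likewise put mice 8134, 8135, 8136 and 8152 on 1 side. Mice 256, 257, 258, 9489 and 9490 were on the other.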

How the results depend on the processing

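The alternatives chosen after seeing the data were edgeR, DESeq2, the omission of the 4 libraries high in Gm42418 or of mouse 9489, and the terms for tissue scores; the others were fixed beforehand. Animal ID numbers pair no mice across groups, so no paired test was run. Where a value changed, the cause was not tested unless given. Khdrbs3 passed at both times under every alternative, including each mouse left out (0.713 to 0.815 short term, 0.640 to 0.722 long term). For the short-term genotype count of 12, the alternatives gave 1 with no filter, 4 with the compared groups alone (fewer libraries; 3 higher, 1 lower, 2 among the 12), 55 with library weights (16 higher, 39 lower), 19 with the ID range as a term, 7 by edgeR, 41 by DESeq2, 24 without the 4 libraries, and 1 with the adrenal score or all 3 scores as terms. Leaving out each mouse gave 1 (9957, 256, 257 or 258) to 21 (9955), with 6 without 10 or 8754, 4 without 9958 and 3 without 8991. The long-term count of 1 was 2 with no filter and 1 to 1 over mice left out. The interaction count of 0 was 6 by DESeq2 and 1 without the 4 libraries, and 0 to 0 over mice left out. In ieCre the time count of 480 was 316 with no filter, 2220 with library weights, 794 by DESeq2, 266 without the 4 libraries, 229 with the adrenal score and 20 with all 3 scores (3 higher, 17 lower), and 272 (without 9485) to 592 (without 10) over mice left out, with 317 without 9955, 290 without 9958, 275 without 9486 and 285 without 9491. In ieET-1 the 1260 became 657 with the compared groups alone, 1898 by DESeq2, 603 without the 4 libraries, 503 with the adrenal score and 117 with all 3 scores, and 698 (without 258) to 1566 (without 9489) over mice left out, with 813 without 8136. Lists past the threshold (3, 5, 2, 10 and 9 in the order of the comparisons) were 0 in all 5 with an estimated correlation, and 0, 0, 0, 7 and 5 by fry, where the 7 were among the 10. With the ID range 8 lists passed in the interaction, and without the 4 libraries 4. Without mouse 9489 3 passed for genotype at the long term and 0 in the interaction. With the adrenal score 7 passed at the short term and 1 in the interaction. Over mice left out, the lists ran from 2 to 4 (short term), 3 (8136, 9489 or 9490) to 7 (long term), 0 (9489) to 4 (8754 or 9958) with 1 without 8987 or 9487 (interaction), 8 to 12 (ieCre) and 8 to 10 (ieET-1). The 1 gene shared by the genotype comparisons was 1 to 1, and the Pearson r of their fold changes ran from -0.18 (without 8134) to 0.28 (without the 4 libraries) over all alternatives. Over mice left out, Edn1 ran from 0.236 to 0.362 (short term) and -0.098 to 0.058 (long term), and Vegfa from -0.208 to -0.044 and -0.045 to 0.086. Neither passed anywhere, and signs near 0 turned: Edn1 at the long term was 0.104 without the 4 libraries, 0.006 with all 3 scores, and 0.021, 0.016, 0.013 and 0.058 without 8089, 9485, 9491 and 8135. Vegfa at the long term was -0.045 with the ID range, -0.035 without the 4 libraries, and -0.045 and -0.017 without 9486 and 8135, and at the short term 0.003 with the adrenal score. Genes that enter the adrenal score or follow it turned when it was a term, by construction for the former: at the short term Hsd3b1 was 0.316, Cyp11b1 0.026 and Cyp11a1 0.240, and with all 3 scores Hsd3b1 was 0.258 and Cyp11a1 0.288. In the interaction Cyp11b1 was -0.071, and with all 3 scores Star was -0.012 and Srd5a2 -0.042. Acta2 in the interaction was -0.194 after quantile normalization, and Pnlip at the long term was -0.28 without the 4 libraries. Of the values of single named genes other than the genotype effects of Edn1, Vegfa and Khdrbs3, 835 stayed on their side of the threshold under the alternatives fixed beforehand other than leaving out mice, 56 lost and 15 gained a call and 1 turned. Over mice left out 1387 stayed, 190 lost and 7 gained a call and none turned, and under the alternatives added later 572 stayed, 112 lost, 15 gained and 9 turned. Under median-of-ratios scaling and quantile normalization the median log2 change of all genes stayed between -0.025 and 0.013. A depth of 9635250 to 16181605 reads limits genes near the floor, such as Cyp11b2, whose fold changes rest on few reads.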

Other observations

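The contrasts between animal ID ranges and the averages over both times in this part were chosen after the data had been seen. Within the long term, libraries of the 80xx to 81xx range differed from those of the 94xx range in 3361 genes, 1693 higher and 1668 lower (limma, genotype held in the model), more than any contrast of genotype or time. Of 12 macrophage markers, 10 were lower in 80xx to 81xx (median log2 -0.86, camera adjusted p = 4.68e-05; adjusted p = 0.542 with an estimated correlation). Immediate early genes, which respond within minutes to stimulation or handling, were higher for 6 of 12 (median 0.71, adjusted p = 8.29e-05), and VEGF ligands and receptors for 5 of 10 (median 0.45, adjusted p = 0.000338), both with adjusted p = 0.503 with an estimated correlation. Endothelial markers were higher for 6 of 13 (median 0.32, adjusted p = 0.023; adjusted p = 0.572 with an estimated correlation) and peripheral nerve markers for 6 of 9 (median 0.51, adjusted p = 0.0303; adjusted p = 0.503 with an estimated correlation). Mitochondrially encoded transcripts were lower for 5 of 6 (median -0.56, adjusted p = 0.00561, and 0.542 with an estimated correlation). Cell cycle (median -0.85, camera adjusted p = 0.00115), interferon (-0.47, 0.023), erythroid (-1.08, 0.0247) and redox lists (-0.25, 0.0388) also lay lower. Adipocyte markers lay higher (0.39, 0.0388). None of these passed with an estimated correlation (lowest adjusted p = 0.572). Of the long-term libraries high in Gm42418, 8135 and 8136 belong to 80xx to 81xx and 9491 to 94xx. At the short term the ranges differed in 1047 genes, 507 higher and 540 lower in mice of 1 to 3 digits. There 5 of 12 genes of the unfolded protein response were higher (median 0.29, camera adjusted p = 0.00694) and 3 of 10 VEGF genes lower (median -0.32, adjusted p = 0.0024). Immediate early genes (-0.49, 0.00267) and endothelial (-0.25, 0.00443), adipocyte (-0.39, 0.0114), nerve (-0.43, 0.0114) and erythroid markers (-0.78, 0.0327) also lay lower. Cell cycle (0.66, 0.00538), macrophage (0.37, 0.00694) and heat shock lists (0.28, 0.044) lay higher. None of these lists passed with an estimated correlation (adjusted p = 0.497 for the unfolded protein response, lowest 0.473).

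Averaged over both times, 3 genes differed between the genotypes, 2 higher and 1 lower (limma): Khdrbs3 (log2 0.73, adjusted p = 1.31e-07), Ssbp4 on chromosome 8 from 70597490 to 70608872 (-0.46, adjusted p = 0.00349) and Rpl3-ps1 on chromosome X from 13202571 to 13203780 (1.93, adjusted p = 0.00349). Rpl3-ps1 exceeded 4 in 6 of 6 ieET-1 and 0 of 6 ieCre libraries at the short term, and in 5 of 6 and 1 of 6 at the long term. The parent gene Rpl3, on chromosome 15 at 80.08 Mb, was at 275 ± 46.6 and 233 ± 33.1 at the short term and 311 ± 69.2 and 268 ± 38.8 at the long term, ieCre first (SD, n = 6 each). Reads of Rpl3-ps1 can be shared with Rpl3, so they need not arise on chromosome X. The nearest tested genes on either side of Khdrbs3 (68.9 Mb on chromosome 15), Gm20732 at 68.34 Mb and Gm23217 at 72.26 Mb, had moderated t values of 0.11 and 0.60 (limma, mean of both times). Within 3 Mb, Tg at 66.7 Mb (-0.75, adjusted p = 0.194) and St3gal1 at 67.1 Mb (-0.24, adjusted p = 0.571) did not pass. Farther away, Ly6e at 75.0 Mb (-0.62, limma adjusted p = 0.0946) and Ly6c2 at 75.1 Mb (0.99, adjusted p = 0.127), both members of the Ly6 surface protein family, did not pass, nor did Zfp251 at 76.9 Mb (-0.25, adjusted p = 0.127) or Tmem117 at 94.6 Mb (0.70, adjusted p = 0.225). Of the chromosome 15 genes with an unadjusted p under 0.01 (limma, mean of both times), all but Nadk2 at 9.1 Mb started between 66.7 and 102.1 Mb. Khdrbs3 lies in that part, and so do many tested genes without such a p. Whether the genes cluster there was not tested.

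Genes of the adrenal medulla, which makes catecholamines, were high in 1 ieCre long-term library, mouse 8088. Its Chga value was 158.8, its value of Th, the first enzyme of catecholamine synthesis, 65.28, and its Pnmt value 16.85, where the next highest in the group were 19.9, 3.66 and 0.949. Without it Chga averaged 7.47 ± 7.45 and Th 1.36 ± 1.32 in that group (SD, n = 5), against 6.38 ± 1.99 and 1.44 ± 0.748 in ieET-1 long term (SD, n = 6). The library was singled out after its values were seen. Sympathetic nerves also express Chga and Th, so these genes alone cannot tell nerve from medulla. Pnmt was high in the same library as well, and the source of the reads was not tested.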
